A study of Mus musculus with 5 samples.

How the data were processed

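Lymph nodes of C57BL/6J mice were profiled by single-cell RNA sequencing on the BD Rhapsody platform, which captures cells in microwells with barcoded beads. Per the labels, CD45-negative cells were enriched by magnetic-activated cell sorting (MACS) and mixed back with CD45-positive cells before loading, so the share of stromal cells in a library depends on the mix. There were 5 libraries, 1 per group. The groups were a normal node without treatment (control) and tumour-draining nodes taken 2 or 4 weeks after implantation of melanoma cells, treated with phosphate-buffered saline (PBS) or with 2'3'-cGAMP at each time. Groups were taken from the labels alone.

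The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell. Per the file headers they came from the BD Rhapsody WTA Analysis Pipeline 1.10.1 with bead version Original (V1), recursive substitution error correction of UMIs, refined cell calling on mRNA, and GRCm38 with a GENCODE annotation. Per the submitters' processing notes, R 4.0.3 and Seurat 3.2.3 were used downstream, and no such processed object was used here. Gene coordinates were taken from GENCODE M21 on GRCm38, a release later than that in the file headers, so genes were matched by symbol.

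From these counts, barcodes with at least 200 genes, at least 500 UMIs and at most 25% of UMIs from mitochondrial genes passed. Scrublet in scanpy 1.11.5 scored doublets with 30 components and an expected rate of 0.1. Its automatic threshold would have called 0.01%, 25.60%, 11.79%, 20.60% and 3.62% of cells in control, PBS week 2, cGAMP week 2, PBS week 4 and cGAMP week 4. The highest scores were therefore removed at the rate that Poisson loading of 200000 microwells gives, which was 2.00%, 4.94%, 3.83%, 14.71% and 6.45%, a rule set after the scores were seen. The 119536 cells left were normalised to 10000 UMIs, log-transformed and scaled with values clipped at 10. Leiden clustering (leidenalg 0.10.2) on 2500 variable genes, 40 principal components and 20 neighbours at resolution 1.5 gave 37 clusters. Clusters were named from 26 marker lists fixed before the data were examined, by the mean log2 ratio of the markers against all other cells. The mean had to reach 2.0 for most classes and 0.5 for T-like and B-like cells, with at least 3 markers raised by 0.5 or more. The endothelial cluster of 397 cells was clustered again on 1500 genes, 15 components and 10 neighbours at resolution 1.0, which gave 13 sub-clusters. Lymphatic-like sub-clusters needed a mean of 0.7 and high endothelial venule (HEV)-like ones 0.5. Sub-clusters with a mean of 1.5 for an immune class were set aside as mixed, and those with 1.5 for reticular or pericyte markers were named for these. These resolutions and thresholds were chosen after the data were seen, and sub-clusterings at other resolutions were viewed and not used. Classes are therefore called "-like" and are rebuilt from RNA alone.

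Counts were summed over the cells of a class in a library and given as CPM, the UMIs of a gene scaled to the UMIs of the whole class. The 5 comparisons were PBS over control at each time, cGAMP over PBS at each time, and PBS week 4 over PBS week 2. With 1 library per group no pair has a replicate, so single pairs carry no test and no number of changed genes. In an alternative added after the data were seen, edgeR's quasi-likelihood method fitted treatment with week as a block to the 4 tumour libraries, which leaves 1 residual degree of freedom and takes its spread largely from other genes. On simulated libraries with 200 genes changed 8-fold and a dispersion of 0.1 it called 198 of them and 11 of the other genes among 7908 tested, at a Benjamini-Hochberg adjusted p under 0.05. Single genes carry exact Poisson intervals, ratios carry conditional binomial intervals and shares carry Clopper-Pearson intervals, each at 95% and for counting error only. A gene with 0 UMIs in a library was given a lower bound against a floor of 3 counts in that library. The minimum fixed beforehand was 50 cells of a class in both libraries. Among endothelial cells only cGAMP over PBS at week 2 met it. The other endothelial pairs, and plasmacytoid dendritic-like cells at week 2, rest on a minimum of 20 cells added after the cell numbers were seen. Lymphatic-like and reticular-like cells were too few, and T-like cells of no clear subset were too mixed, to be compared.

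For a gene list the median log2 ratio over its measured members was taken, with 0.5 counts added. A member was measured with at least 20 UMIs in the pair, and a list needed 5 such members. Each median was placed among 10000 random lists matched on expression in 10 bins, and this percentile describes these libraries alone. The 21 lists, fixed before the data were examined, covered type I interferon response, interferon gamma-induced genes, MHC class I and class II presentation, the HEV programme, leukocyte adhesion, inflammatory NF-kB targets, the cGAS-STING pathway, angiogenesis and tip cells, proliferation, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, dissociation and immediate early genes, extracellular matrix, cholesterol synthesis, lymphocyte chemoattractants, T cell checkpoint molecules, cytotoxic effectors, T cell exhaustion and melanoma cells.

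The genes named in the text follow a rule fixed before the data were examined. In blood endothelial-like cells the 8 genes with the highest and the 8 with the lowest ratio of each pair are named, and in HEV-like cells 5 of each. They needed at least 100 CPM and 30 UMIs in the higher library, a ratio interval that excludes 1.5-fold, and a CPM no lower than that of the highest immune-like class divided by 4. Mitochondrial, ribosomal, immunoglobulin, T cell receptor variable, haemoglobin, unnamed and sex-linked marker genes were left out. Up to 4 members with the highest mean CPM are named for each list. Some genes that this rule selects are not reported here. Tmem173, Pecam1, Cdh5 and Kdr are given in every library. Other genes named, such as Ifnb1, Ifng and Cxcl9 outside blood vessels, were chosen after their values were seen.

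The calculation was tested on simulated data drawn from the real means of each pair, with 100 genes raised 2-fold and 100 lowered 4-fold. The intervals held the true ratio for 96.0% to 97.1% of genes. Counts were drawn as independent Poisson values per gene, which the intervals assume, so this checks the calculation alone. Spread between cells and genes that vary together were not simulated. The median of raised genes was 0.94 to 1.02 and that of lowered genes -2.08 to -1.98 on the log2 scale. Between 1 and 6 of 100 lists of unchanged genes fell outside the central 95% of random lists. Alternatives changed the filters on cells (500 genes and 1000 UMIs, or 10% mitochondrial UMIs), kept the doublets, lowered the sub-clustering resolution to 0.5, averaged CPM over cells, scaled with TMM factors, left out mitochondrial, ribosomal and immunoglobulin genes, subtracted free RNA, required 100 UMIs per list member, added 5 counts, or left out HEV-like cells. Free RNA is RNA from broken cells that enters the wells of others. Its share was estimated from immunoglobulin genes at 4.523%, 2.011%, 1.58%, 7.761% and 2.995% of the UMIs of endothelial cells in the order above, and from haemoglobin genes at 8.903%, 223.2%, 3.007%, 0.9786% and 3.133%. The value above 100% arose because some PBS week 2 endothelial cells carried haemoglobin RNA, and the lower estimate of each library was subtracted, or in an alternative added after the data were seen the immunoglobulin estimate of each. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors and the fit with week as a block.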

Results

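Lymph node cells were sequenced from 5 groups of mice, 1 library each, to compare blood vessel endothelium and immune cells of a normal node with those of tumour-draining nodes, with and without a STING agonist. STING, encoded by Tmem173, senses the cyclic dinucleotide 2'3'-cGAMP that cells make on contact with cytosolic DNA, and it activates the transcription of interferon genes. After filtering, the libraries held 7903 cells in the control, 19101 in PBS week 2, 14932 in cGAMP week 2, 52918 in PBS week 4 and 24682 in cGAMP week 4. These cells carried 58001516, 73166712, 65395390, 107695271 and 78204801 UMIs in total. The median per cell was 5716, 2591, 2998, 1244 and 2393 UMIs in the same order, so the cells of PBS week 4 were the shallowest. No group had a replicate, so differences below describe single libraries. Intervals in parentheses are 95% intervals for counting error only, except that those of a median describe the spread over list members.

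Blood endothelial-like cells numbered 31 in the control, 83 in PBS week 2, 82 in cGAMP week 2, 31 in PBS week 4 and 30 in cGAMP week 4, with 246957, 784618, 878388, 244852 and 211012 UMIs in all. HEV-like cells, whose RNA resembles the venules through which lymphocytes enter the node, made up 80.7% (62.5 to 92.6) of them in the control. Their share was 63.9% (52.6 to 74.1) in PBS week 2, 62.2% (50.8 to 72.7) in cGAMP week 2, 22.6% (9.59 to 41.1) in PBS week 4 and 23.3% (9.93 to 42.3) in cGAMP week 4. Lymphatic-like cells made up 18.4% (7.74 to 34.3), 13.5% (7.41 to 22), 6.82% (2.54 to 14.2), 11.4% (3.2 to 26.7) and 16.7% (6.37 to 32.8) of endothelial cells. Sub-cluster 9, with 20 of these cells, 12 of them from PBS week 2, had a mean log2 fold of 0.77 for lymphatic markers against 2.89 in sub-cluster 11 and none of them among its 10 leading genes, so its name is uncertain. These shares followed enrichment of CD45-negative cells by MACS and mixing with CD45-positive cells, and no direction is drawn from them. HEV-like cells lay mostly in sub-cluster 3 in the control (84%), in sub-cluster 0 in PBS week 2 (62.3%) and PBS week 4 (85.7%), and in sub-cluster 2 in cGAMP week 2 (76.5%) and cGAMP week 4 (71.4%). Further cells of the endothelial cluster were set aside as mixed with B-like cells (3, 13, 6, 5 and 0 cells in the order of the libraries) or with CD8 T-like cells (0, 7, 5, 2 and 3).

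Tmem173 was read in blood endothelial-like cells of every library, at 154 CPM (109 to 211) in the control, 260 (226 to 298) in PBS week 2, 347 (309 to 388) in cGAMP week 2, 212 (159 to 278) in PBS week 4 and 275 (209 to 355) in cGAMP week 4. In HEV-like cells Tmem173 stood at 175, 345 and 412 CPM in the control, PBS week 2 and cGAMP week 2. Macrophage- or monocyte-like cells held 85.2, 111, 252, 125 and 168 CPM of it, and B-like cells 106, 97.3, 79.1, 70.9 and 58.7 CPM. Pecam1, an adhesion molecule of endothelial junctions, was at 3410 CPM (3183 to 3648), 2971 (2851 to 3094), 2684 (2577 to 2795), 1723 (1563 to 1896) and 2559 (2348 to 2784). Cdh5, the cadherin of those junctions, was at 891 CPM (777 to 1017), 761 (701 to 824), 1039 (973 to 1109), 735 (632 to 851) and 1299 (1149 to 1462). Kdr, a receptor for vascular endothelial growth factor, was at 960 CPM (841 to 1090), 1161 (1087 to 1239), 855 (795 to 918), 2009 (1836 to 2195) and 1711 (1539 to 1897). On GRCm38, Tmem173 lies on chromosome 18 from 35733679 to 35740554, Pecam1 on chromosome 11 from 106654217 to 106750628, Cdh5 on chromosome 8 from 104101625 to 104144511 and Kdr on chromosome 5 from 75932827 to 75978458. No UMI of Ifnb1, the gene for interferon beta, was read in blood endothelial-like cells of any library. The floor of 3 counts corresponds to 12.2, 3.82, 3.42, 12.3 and 14.2 CPM.

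The comparison of cGAMP with PBS at week 2 asks how vessels of the draining node differ under the STING agonist. Interferon-induced genes stood out among the genes higher with cGAMP in blood endothelial-like cells. They included antiviral genes, GTPases and the chemokines Cxcl9 and Cxcl10 that attract activated T cells. Genes of antigen presentation were higher with cGAMP, for both MHC class I and class II. Genes of cell division were lower with cGAMP, and they came from few cells. The list of transcripts that mark high endothelial venules lay among the random lists, though Ubd and Ackr1 in it were higher.

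The type I interferon list had a median log2 ratio of 2.61 with all 34 measured members higher in cGAMP week 2, above all of the 10000 matched random lists (percentile 100). Slfn5 stood at 1508 CPM with cGAMP and 696 with PBS, 2.17-fold higher (1.96 to 2.4). Bst2, which tethers budding virus, was 3.99-fold higher (3.53 to 4.53), Ifi44 4.21-fold (3.65 to 4.88) and Ifi203 3.39-fold (2.93 to 3.92). The interferon gamma-induced list had a median of 2.60 with 22 of 23 members higher (percentile 100). Its most abundant member was Cxcl9, with 8447 CPM against 25.5, which was 331-fold higher (214 to 543). Cxcl10 was at 1984 against 48.4 CPM, Gbp2 at 2165 against 91.8 CPM and Iigp1 at 2247 against 402 CPM. Cxcl9 and Cxcl10 are neighbours on chromosome 5 of GRCm38, from 92321347 to 92328079 and from 92346638 to 92348889. In the cGAS-STING pathway list, whose median was 0.05 (percentile 84.81), Irf7 was 17.1-fold higher (12.7 to 23.4), Ifi204 12.8-fold higher (8.66 to 19.7) and Tmem173 itself 1.34-fold higher (1.12 to 1.60).

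Every one of the 19 members of the MHC class I list was higher with cGAMP at week 2, with a median of 1.20 (percentile 100). B2m, the light chain, was 1.68-fold higher (1.62 to 1.73), H2-D1 and H2-K1 both 1.76-fold, and Tapbp, which loads peptide, 2.76-fold (2.45 to 3.11). For MHC class II all 6 measured members were higher, with a median of 1.09 (percentile 99.92), or 2.02 with free RNA subtracted. Regulatory T-like cells had a class II median of 0.92 in the same pair, so RNA from other cells may enter these values. Cd74 stood at 732 against 245 CPM, H2-Ab1 at 181 against 72.7 CPM and H2-Aa at 146 against 79.0 CPM. T cell checkpoint molecules had a median of 0.51 (percentile 99.47), with Cd274, the ligand PD-L1, at 367 against 56.1 CPM and Lgals9 at 1332 against 403 CPM. Leukocyte adhesion genes had a median of 0.27 (percentile 98.85), with Cd47 2.93-fold higher (2.62 to 3.29). Lymphocyte chemoattractants had a median of 0.54 (percentile 99.71), with Il15 3.36-fold higher (2.42 to 4.76) but Cxcl12 1.93-fold lower (1.65 to 2.25). In the HEV programme, Ubd stood at 8352 against 4087 CPM and Ackr1 at 1149 against 463 CPM, while Glycam1, the sulphated ligand of L-selectin, was 1.06-fold lower (1.03 to 1.09) and Ccl21a 1.23-fold lower (1.17 to 1.29).

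The median over all genes in this pair was -0.16, so lists near that value hardly differ from other genes. The HEV programme (-0.06, percentile 57.66), inflammatory NF-kB targets (-0.09, 63.31), angiogenesis (-0.05, 70.31) and extracellular matrix (-0.03, 72.47) were such lists, and with TMM factors their medians were 0.15, 0.12, 0.16 and 0.18. Among their members Irf1 was 2.09-fold higher (1.69 to 2.59) and Timp3 2.07-fold higher (1.87 to 2.30), and Sparc was 1.68-fold lower (1.59 to 1.77). Oxidative phosphorylation had a median of -0.52 (percentile 0) with Cox6c 1.5-fold lower (1.29 to 1.74), and ribosomal proteins one of -0.35 (percentile 0). With TMM factors these medians were -0.31 and -0.13. Oxidative phosphorylation was -0.71 with HEV-like cells left out, and ribosomal proteins -0.43 with mitochondrial, ribosomal and immunoglobulin genes left out of the CPM total. Hypoxia and glycolysis stood at 0.20 (percentile 99.22) with Pkm 1.74-fold higher (1.49 to 2.02), cholesterol synthesis at -0.41 (20.74) with Srebf2 2.45-fold lower (1.43 to 4.33). Dissociation and immediate early genes had a median of -0.28 (percentile 4.38), with Fos 1.70-fold lower (1.51 to 1.91) but Hspb1 2.69-fold higher (2.48 to 2.91).

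Proliferation genes were lower with cGAMP at week 2, with a median of -3.41 and 0 of 28 members above 0, or -3.23 with the 5 members at 0 in a library set to their bound. In PBS week 2 they came from few cells, since 4 of the 83 cells held 72.5% of the 1466 UMIs of the list. Without sub-cluster 7, which held 7 cells of PBS week 2 and 0 of cGAMP week 2, the median was -1.11. At an equal depth of 1000 UMIs per cell, 11 of 78 cells in PBS week 2 (14.1%, 7.26 to 23.8) and 2 of 82 in cGAMP week 2 (2.44%, 0.297 to 8.53) held at least 2 genes of the list. At full depth the shares went the other way, at 44.6% (33.7 to 55.9) and 51.2% (39.9 to 62.4). Median UMIs per cell were then 8007 and 10774. Top2a was at 1.14 against 140 CPM, Mki67 at 7.97 against 153 CPM, Stmn1 at 20.5 against 224 CPM and Cks2 at 7.97 against 108 CPM. Other genes lower with cGAMP were Btnl9, 20.5-fold (10.6 to 45.7), the retinol carrier Rbp7, 7.56-fold (4.10 to 15.2), the lipase Mgll, 7.01-fold (4.65 to 11) and Igfbp4, 5.56-fold (3.81 to 8.35). Btnl9, Rbp7 and Mgll are leading genes of sub-cluster 8, which held 11 cells of PBS week 2 and 0 of cGAMP week 2. Of the cells that were not HEV-like, 77.4% in cGAMP week 2 lay in sub-cluster 4, which held 0 PBS cells. Beyond the chemokines and Gbp2, the genes furthest above PBS were AA467197 with 151 against 1.27 CPM, 119-fold higher (21.0 to 4727), the metallothionein Mt2 with 347 against 5.10 CPM, Phf11b with 498 against 10.2 CPM, Apol9a with 100 against 2.55 CPM and Ms4a4d with 316 against 10.2 CPM.

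**Figure D1:**
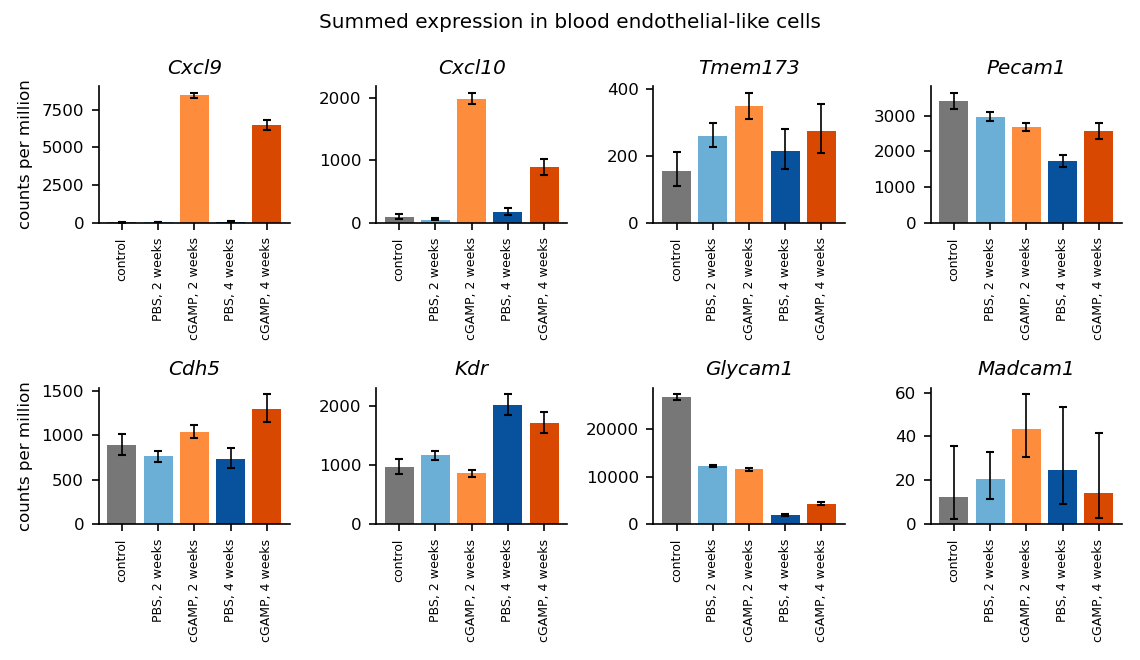
CPM of 8 genes (linear axes, 1 scale per gene) in blood endothelial-like cells of the 5 libraries, with bars for 95% Poisson intervals. Cxcl9 stands at 8447 CPM in cGAMP week 2 and 6469 CPM in cGAMP week 4, against 69.4 CPM or less in the other libraries.

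Within HEV-like cells the same interferon difference was seen at week 2, with a type I interferon median of 2.19 over 33 members, all higher, and an interferon gamma-induced median of 2.32 with 20 of 21 higher, both at percentile 100. Cxcl9 was at 6176 against 21.9 CPM and Gbp5 at 793 against 45.6 CPM. Serping1, an inhibitor of complement, was at least 19.1-fold higher, but its log2 ratio was 3.2 at a sub-clustering resolution of 0.5 and 2.20 with clusterings made without the interferon lists. Mt2 was 40.1-fold (15.4 to 149) and Fjx1 23.5-fold (7.76 to 116) higher. Ackr1, a chemokine-binding receptor of venules, was 2.41-fold higher (2.13 to 2.72), and the HEV programme as a whole had a median of 0.15 (percentile 94.70). The markers that named HEV-like sub-clusters, Ackr1 among them, all belong to this list, so their level within the class is partly set by its selection. Sub-cluster 2, led by Ackr1, held 39 cells of cGAMP week 2 and 0 of PBS week 2. MHC class I (1.05, percentile 100), MHC class II (1.07, 99.83) and checkpoint molecules (0.72, 99.89) were higher, while the dissociation list was lower (-0.54, percentile 0). Lower single genes in HEV-like cells were Igfbp4, 4.90-fold (3.30 to 7.50), Egr1, 4.4-fold (3.4 to 5.76), Cxcl1, 4.18-fold (2.58 to 7.03), Tagln, 4.14-fold (2.39 to 7.55) and Sema5a, 3.95-fold (2.46 to 6.58). Of the Egr1 UMIs, 51.9% came from 1 cell of PBS week 2.

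The same comparison at week 4 asks whether vessels differ under the agonist in later nodes, on 30 and 31 blood endothelial-like cells. The PBS library of this pair alone held melanoma-like cells, and whether some of its vessel cells came with tumour tissue cannot be told. Interferon-induced genes and MHC class I genes again stood higher with cGAMP. Most MHC class II genes were lower with cGAMP at this time, and so was the B cell transcript Igkc. Several HEV transcripts were higher with cGAMP. The angiogenesis list lay among the random lists, though single genes such as Esm1 were lower.

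All 30 measured members of the type I interferon list were higher in cGAMP week 4, with a median of 2.87 (percentile 100). Rsad2, the antiviral enzyme viperin, stood at 1426 against 4.08 CPM, 349-fold higher (62.2 to 13841). Slfn5 was 3.45-fold higher (2.77 to 4.32), Ifi203 5.31-fold (4.04 to 7.08), Bst2 5.62-fold (4.22 to 7.59) and Ifi44 7.96-fold (5.74 to 11.3). The interferon gamma-induced list had a median of 2.32 with 19 of 21 members higher (percentile 100), with Cxcl9 at 6469 against 69.4 CPM, Gbp2 at 1412 against 44.9 CPM, Iigp1 at 1701 against 380 CPM and Cxcl10 at 886 against 176 CPM. MHC class I had a median of 1.59 with 18 of 18 higher (percentile 100), with H2-K1 3.0-fold higher (2.71 to 3.34) and Tapbp 4.24-fold (3.25 to 5.58). The cGAS-STING list stood at 0.49 (percentile 97.29), with Irf7 at 1332 against 40.8 CPM, Ifi204 15.6-fold higher (7.27 to 39.8) and Tmem173 1.29-fold higher (0.875 to 1.92), an interval that includes no difference. Further genes high with cGAMP were Isg20 with 645 against 8.17 CPM, Ms4a4d with 630 against 8.17 CPM, Serping1 with 436 against 8.17 CPM, Usp18 with 237 against 4.08 CPM and Ifi211 with 336 against 8.17 CPM. Serpina3n was 63.8-fold higher (11 to 2566), with 50.9% of its UMIs in 1 cell.

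MHC class II had a median of -0.84 at week 4 with 1 of 5 members higher (percentile 0.62) and an interval of -1.34 to 1.27 that spans 0. It was -1.64 with free RNA subtracted as planned, and -0.57 at the immunoglobulin estimate of each library. Igkc stood at 313 against 580 CPM, so RNA from B-like cells may enter this value. Cd74 stood at 422 CPM with cGAMP and 760 with PBS, H2-Aa was 2.56-fold lower (1.72 to 3.90) and Ctss 2.44-fold higher (1.40 to 4.38). The HEV programme had a median of 0.58 with 17 of 21 members higher (percentile 99.93), with Ubd at 4805 against 1286 CPM, Ccl21a at 3298 against 1242 CPM and Glycam1 at 4260 against 1960 CPM. Leukocyte adhesion stood at 0.42 (percentile 97.97) with Pecam1 1.49-fold higher (1.30 to 1.69). Chemoattractants stood at 1.19 with 6 of 6 higher (percentile 99.72), among them Cxcl12 at 559 against 286 CPM and Il15 at 199 against 4.08 CPM. Checkpoint molecules had a median of 0.74 (percentile 98.96), with Lgals9 4.06-fold higher (3.19 to 5.21). Oxidative phosphorylation was at -0.70 (percentile 0) with Cox7c 1.72-fold lower (1.32 to 2.27), hypoxia and glycolysis at -0.44 (3.56) with Aldoa 2.20-fold lower (1.59 to 3.10), and ribosomal proteins at -0.27 (4.02) with Rps29 1.86-fold lower (1.64 to 2.11). With TMM factors oxidative phosphorylation stood at -0.54 and ribosomal proteins at -0.11. With HEV-like cells left out oxidative phosphorylation stood at -0.83. NF-kB targets (0.18, percentile 86.09), extracellular matrix (-0.17, 30.36) and immediate early genes (-0.06, 52.48) lay among the random lists, with Hspb1 at 1635 against 392 CPM, and cholesterol synthesis had too few measured members.

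Angiogenesis genes had a median of -0.23 at week 4 (percentile 13.88), with Sparc 1.80-fold lower (1.67 to 1.95) and Plvap 1.12-fold higher (1.01 to 1.25). Esm1, a marker of endothelial tip cells, stood at 42.7 against 486 CPM, 11.4-fold lower (5.80 to 25.5), the potassium channel subunit Kcne3 at 9.48 against 310 CPM and the endothelin receptor Ednrb at 37.9 against 735 CPM. Mest was at least 18.1-fold lower, and S100a6 6.29-fold lower (4.38 to 9.28). Kcne3, Mest and Esm1 are leading genes of sub-cluster 7, which held 12 cells of PBS week 4 and 2 of cGAMP week 4, while sub-cluster 8 held 8 and 0 and sub-cluster 4 held 0 and 13. All Rgs5 UMIs of PBS week 4 (100%) and 93.3% of its Cxcl1 UMIs lay in 1 cell each, and these genes were 14.7-fold (3.76 to 126) and 38.8-fold (6.61 to 1565) lower with cGAMP. With HEV-like cells left out their log2 ratios were 2.64 and -1.27, and that of Rgs5 was -0.61 at a sub-clustering resolution of 0.5. Proliferation had a median of -1.02 with 1 of 16 members higher (percentile 0), with Pclaf 25.9-fold lower (4.30 to 1055), Stmn1 at 33.2 against 180 CPM and Mki67 at 42.7 against 135 CPM. Of the list's UMIs, 75.9% of 530 lay in 4 cells in PBS week 4 and 81% of 200 in cGAMP week 4. At equal depth 6 of 30 cells (20%, 7.71 to 38.6) and 2 of 30 (6.67%, 0.818 to 22.1) held at least 2 genes of the list. At full depth the shares were 64.5% (45.4 to 80.8) in PBS week 4 and 46.7% (28.3 to 65.7) in cGAMP week 4.

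**Figure D2:**
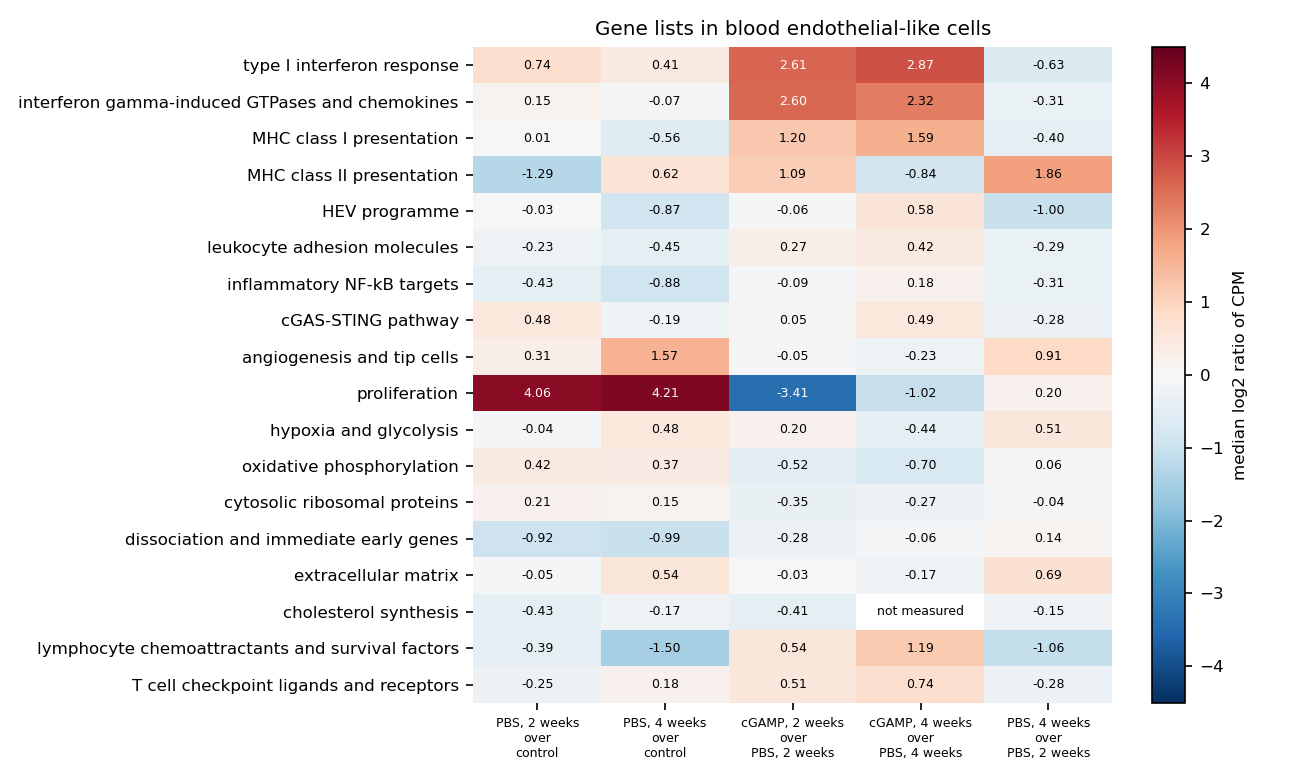
Heat map of the median log2 ratio of CPM for each gene list in blood endothelial-like cells, with 1 column per pair of groups. For cGAMP over PBS at weeks 2 and 4 the type I interferon medians are 2.61 and 2.87, and the MHC class II medians 1.09 and -0.84.

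PBS week 2 against the control asks how vessels of an early tumour-draining node differ from those of a normal node. Genes of cell division were higher in the draining node in a few cells. Glycam1 and other abundant HEV transcripts were lower, while Ubd was higher. Immediate early genes and NF-kB targets were higher in the control. The type I interferon list was modestly higher in the draining node, and the interferon gamma-induced list lay among the random lists.

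In this pair the type I interferon list had a median of 0.74 with 23 of 25 members higher in blood endothelial-like cells (percentile 100), or 0.44 with CPM averaged over cells, with Ifi44 at 288 against 44.5 CPM and Ifi203 1.64-fold higher (1.19 to 2.29). The interferon gamma-induced list (0.15, percentile 83.77) and MHC class I (0.01, 48.59) lay among the random lists, with B2m 1.01-fold higher (0.953 to 1.06). MHC class II was lower at -1.29 with 0 of 5 members higher (percentile 0), and H2-Aa stood at 79.0 against 271 CPM. Igkc was lower as well, at 122 against 227 CPM, and the class II median was -2.02 with doublets called by scrublet's own threshold and -2.05 without sub-cluster 7. The HEV programme had a median of -0.03 (percentile 36.23) over members that went both ways, since Glycam1 was at 12172 against 26693 CPM, 2.19-fold lower (2.12 to 2.26), Enpp2 1.47-fold lower (1.38 to 1.57) and Ubd at 4087 against 1421 CPM. NF-kB targets stood at -0.43 (percentile 0.39) with Nfkbia 2.14-fold lower (1.83 to 2.49), and immediate early genes at -0.92 (percentile 0) with Egr1 3.06-fold lower (2.68 to 3.49) and Hspa8 2.20-fold higher (1.90 to 2.57). Adhesion (-0.23, percentile 3.24), chemoattractants (-0.39, 5.32), checkpoint molecules (-0.25, 16.41), cholesterol synthesis (-0.43, 3.05), extracellular matrix (-0.05, 24.27) and hypoxia (-0.04, 34.52) had medians at or below 0, and Vsir was 1.64-fold lower (1.14 to 2.32). The cGAS-STING list (0.48, percentile 98.55), angiogenesis (0.31, 98.72), oxidative phosphorylation (0.42, 99.98) and ribosomal proteins (0.21, 96.88) had medians above 0. Among their members Tmem173 was 1.69-fold higher (1.19 to 2.46), Sparc 1.80-fold (1.65 to 1.97) and Col4a1 1.70-fold (1.51 to 1.92).

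The proliferation list had a median of 4.06 with 25 of 26 members higher in PBS week 2 (percentile 100), yet 17 members had 0 UMIs in 1 library and the median with those at their bound was 1.89. A single control cell decided its size: this cell, placed with lymphatic-like cells, held 273 UMIs of the list, and with it in the class the median was 0.41. At equal depth 1 of 31 control cells (3.23%, 0.0816 to 16.7) held at least 2 genes of the list. At full depth the share was 48.4% (30.15 to 66.94) in the control and 44.6% (33.7 to 55.9) in PBS week 2, so it was not higher in PBS week 2. Mki67 was at 153 against 4.05 CPM and Stmn1 at 224 against 16.2 CPM, while Top2a was at least 11.5-fold and Cks2 at least 8.92-fold higher. Hmgb2 was 4.76-fold higher (2.87 to 8.46), Cacybp 4.37-fold (2.23 to 9.78) and Hmgn2 3.90-fold (1.90 to 9.27). With that control cell in the class the log2 ratios of Top2a, Mki67, Stmn1, Cks2 and Hmgb2 were 0.30, 0.37, 0.41, 1.56 and 1.21. Lower in PBS week 2 were C1qtnf9, 7.59-fold (4.29 to 14.0), the smooth muscle gene Tagln, 5.21-fold (3.78 to 7.23), Tns1, 4.06-fold (2.72 to 6.07), Chp2, 3.77-fold (2.67 to 5.35) and Rasa4, 3.77-fold (2.30 to 6.24). Cytl1, at least 35.0-fold lower, Ptgds, 13.0-fold lower (6.62 to 27.9), and Timp4, 8.10-fold lower (5.57 to 12.0), had 100%, 55.6% and 57.8% of their control UMIs in 1 cell.

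In HEV-like cells of PBS week 2 against the control, on 53 and 25 cells, the type I interferon median was 1.23 with 19 of 21 members higher (percentile 100). Ifi44 was 7.64-fold higher (3.78 to 18.0), Oasl2 4.93-fold (2.41 to 11.7), Nqo2 7.22-fold (2.35 to 36.1) and Lyve1 4.45-fold (2.16 to 10.6), and Ifit3 was 11.8-fold higher (3.13 to 99.6) with 50.8% of its UMIs in 1 cell. With CPM averaged over cells the log2 ratios of Oasl2 and Lyve1 were 1.08 and 0.75, below their intervals. Lyve1 is also among the markers of lymphatic-like cells. The HEV programme had a median of -0.01 (percentile 41.83), with Glycam1 at 17412 against 31109 CPM and Ubd at 5832 against 1656 CPM. Both genes are markers that named the class, so its selection partly sets their level here too. MHC class II stood at -2.08 (percentile 0), NF-kB targets at -0.50 (0.10) and immediate early genes at -1.10 (0). Lower genes were Cytl1, at least 28.4-fold, the fatty acid receptor Cd36, 38.1-fold (18.7 to 90.4) with 50.8% of its UMIs in 1 control cell, Ptgds, 10.6-fold (5.39 to 22.7), C1qtnf9, 8.93-fold (4.47 to 19.4) and Timp4, 6.59-fold (4.53 to 9.76).

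PBS week 4 against the control asks the same of a later draining node, on 31 cells each. Genes of the angiogenesis list stood higher in the PBS week 4 library. Melanoma-like cells were read in this library alone, and whether some of its vessel cells came with tumour tissue cannot be told. HEV transcripts were much lower, in a class that held 7 HEV-like cells against 25. MHC class I genes and the list of lymphocyte chemoattractants and survival factors were lower as well.

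Angiogenesis genes had a median of 1.57 with 21 of 26 members higher in PBS week 4 (percentile 100), with Sparc at 8654 against 2340 CPM, Col4a1 at 4317 against 1348 CPM and Plvap 1.31-fold lower (1.19 to 1.44). Esm1, on chromosome 13 of GRCm38 from 113209659 to 113218098, was at 486 against 8.10 CPM, 60.0-fold higher (16.3 to 501). Kcne3 was at 310 against 4.05 CPM, Tubb6 at 180 against 4.05 CPM and Mest at least 21.2-fold higher. Esm1, Kcne3 and Mest are leading genes of sub-cluster 7, which held 12 cells of PBS week 4 and 0 of the control. Sub-cluster 8 held 8 and 1. Extracellular matrix (0.54, percentile 99.03), hypoxia and glycolysis (0.48, 94.73), MHC class II (0.62, 92.62) and oxidative phosphorylation (0.37, 97.76) had medians above 0, with Gapdh 1.78-fold higher (1.44 to 2.21) and Cd74 2.41-fold higher (1.84 to 3.17). The class II median was 2.10 with free RNA subtracted as planned and 0.16 with the mitochondrial limit at 10%, and Igkc stood at 580 against 227 CPM. Proliferation had a median of 4.21 with 10 of 10 higher (percentile 100), or 3.33 with the 4 members at 0 set to their bound. Ube2c was at least 11.4-fold higher with 94.1% of its UMIs in 1 cell, Birc5 and Cks2 at least 10.8-fold and Pclaf at least 10.1-fold. The same control cell decides these sizes too, since with it in the class the log2 ratios of Ube2c, Birc5, Cks2 and Pclaf were 1.79, 2.19, 1.85 and 2.54 and the median of the list was 0.86.

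The HEV programme stood at -0.87 in PBS week 4 over control with 6 of 23 members higher (percentile 0). Glycam1, on chromosome 15 of GRCm38 from 103562759 to 103565081, was at 1960 against 26693 CPM, 13.6-fold lower (12.4 to 15), Ccl21a 4.94-fold lower (4.37 to 5.61) and Enpp2 3.73-fold lower (3.32 to 4.19). Chemoattractants stood at -1.50 (percentile 0.03) with Il15 at 4.08 against 97.2 CPM, NF-kB targets at -0.88 (0.02) with Nfkbia 1.85-fold lower (1.51 to 2.27), MHC class I at -0.56 (0.24) with H2-K1 1.97-fold lower (1.77 to 2.20) and adhesion at -0.45 (0.81) with Icam1 1.98-fold lower (1.33 to 3.01). Immediate early genes stood at -0.99 (percentile 0) with Fos 2.21-fold lower (1.90 to 2.59). The type I interferon (0.41, percentile 93.82), interferon gamma-induced (-0.07, 33.01), cGAS-STING (-0.19, 24.43), cholesterol (-0.17, 28.86), ribosomal (0.15, 54.84) and checkpoint (0.18, 62.16) lists lay among the random lists, with Slfn5 1.62-fold lower (1.27 to 2.08). Clu, a secreted chaperone, was at 310 against 7645 CPM, the lipid carrier Apoe at 221 against 3053 CPM and Pltp at 44.9 against 660 CPM. Serpina3n was 78.3-fold lower (13.7 to 3132), Sulf1 33.7-fold (5.66 to 1370), Tagln 17.4-fold (7.71 to 48.4), Timp4 at least 33.7-fold and Cytl1 at least 10.9-fold.

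PBS week 4 against PBS week 2 asks how vessels of draining nodes differ between the times. Angiogenesis and matrix genes were higher at week 4, in the library that alone held melanoma-like cells. MHC class II genes were higher as well, together with the B cell transcript Igkc. HEV transcripts and interferon-induced genes were higher at week 2. Genes of cell division did not separate the times.

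Angiogenesis had a median of 0.91 with 24 of 29 members higher at week 4 (percentile 100), extracellular matrix one of 0.69 (percentile 100) and hypoxia and glycolysis one of 0.51 (percentile 99.93). Sparc was 2.05-fold higher (1.94 to 2.17), Col4a1 1.88-fold (1.74 to 2.03) and Kdr 1.73-fold (1.55 to 1.93), and Gapdh was 1.35-fold higher (1.16 to 1.57). Esm1 stood at 486 against 16.6 CPM, Igfbp3 at 2712 against 133 CPM, Kcne3 at 310 against 14.0 CPM, and Apln, the ligand of the apelin receptor, at 441 against 45.9 CPM. Inhbb was 15.7-fold higher (7.86 to 34.8), Ednrb 15.2-fold (10.7 to 22.2), Sat1 10.6-fold (8.49 to 13.2) and Stc1 10.2-fold (7.90 to 13.2). With HEV-like cells left out several of these genes stayed higher but by less, with log2 ratios of 3.59 for Esm1, 3.43 for Kcne3, 3.11 for Igfbp3, 2.92 for Stc1, 2.67 for Ednrb and 2.08 for Apln. MHC class II had a median of 1.86 with 6 of 6 higher (percentile 100), with Cd74 at 760 against 245 CPM and H2-Aa at 412 against 79.0 CPM. Igkc stood at 580 against 122 CPM, and the class II median was 3.22 with free RNA subtracted as planned, 1.65 at the immunoglobulin estimates of 7.761% and 2.011%, and 2.78 with doublets called by scrublet's own threshold.

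The HEV programme had a median of -1.0 at week 4 over week 2 with 5 of 24 members higher (percentile 0), but 0.25 with HEV-like cells left out, and Ccl21a was 3.32-fold lower (2.95 to 3.75). The type I interferon list stood at -0.63 with 5 of 27 higher (percentile 0) and Bst2 1.69-fold lower (1.27 to 2.28), the interferon gamma-induced list at -0.31 (0.52) and MHC class I at -0.40 (0.12). Chemoattractants were at -1.06 (percentile 0.07) with Cxcl12 2.04-fold lower (1.58 to 2.67), NF-kB targets at -0.31 (1.68), adhesion at -0.29 (1.87) and the cGAS-STING list at -0.28 (6.67). Proliferation (0.20, percentile 91.34), oxidative phosphorylation (0.06, 49.92), ribosomal proteins (-0.04, 14.46), immediate early genes (0.14, 80.65), cholesterol synthesis (-0.15, 33.47) and checkpoint molecules (-0.28, 9.17) lay among the random lists, with Mki67 at 135 against 153 CPM. Lower at week 4 were Clu with 310 against 3711 CPM, Glycam1 with 1960 against 12172 CPM, Cd63 with 28.6 against 238 CPM, Pltp with 44.9 against 329 CPM and elastin, Eln, with 24.5 against 154 CPM. Slc16a9 was 6.80-fold lower (2.83 to 21.4), Serpina3n 50.9-fold (9.0 to 2021) and Mustn1 11.9-fold (5.37 to 32.6), but with HEV-like cells left out the log2 ratios of Serpina3n and Mustn1 were 0.44 and 1.66, and that of Clu was -1.02 in place of -3.57.

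Immune cells answer whether the difference with cGAMP was particular to vessels. Interferon-induced genes were higher with cGAMP in each immune class compared. Macrophage- or monocyte-like cells were more frequent with cGAMP, lay mostly in another cluster and carried less MHC class II RNA. NK-like and CD8 T-like cells held more Gzmb, which encodes the protease granzyme B. CD4 T-like, CD8 T-like and B-like cells of PBS week 4 held more Nr4a3 than those of PBS week 2.

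The type I interferon medians for cGAMP over PBS at weeks 2 and 4 were 3.87 and 3.2 in B-like cells, 3.57 and 3.17 in dendritic-like cells, 3.25 and 2.76 in regulatory T-like cells and 3.07 and 2.78 in CD4 T-like cells. They were 2.97 and 2.60 in macrophage- or monocyte-like cells, 2.96 and 2.47 in NK-like cells, 2.72 and 2.37 in CD8 T-like cells and 2.30 and 2.24 in plasmacytoid dendritic-like cells, each with every measured member higher and at percentile 100. Slfn5 in B-like cells was 22.2-fold higher (21.2 to 23.2) at week 2 and 9.67-fold (9.45 to 9.90) at week 4. Isg15 in dendritic-like cells was 28.0-fold (23.6 to 33.3) and 23.1-fold (19.8 to 27.2) higher, and Rsad2 in macrophage- or monocyte-like cells 78.0-fold (60.5 to 102) and 17.1-fold (15.6 to 18.7). For PBS over control the medians lay between 0.41 in NK-like and 1.46 in macrophage- or monocyte-like cells at week 2, and between 0.73 in CD4 T-like and 1.70 in macrophage- or monocyte-like cells at week 4. Cxcl9 stood at 4236 and 991 CPM in macrophage- or monocyte-like cells with cGAMP and at 899 and 599 CPM in dendritic-like cells. Ifng, which induces it, was at 76.9, 199, 976, 133 and 436 CPM in NK-like cells of control, PBS week 2, cGAMP week 2, PBS week 4 and cGAMP week 4. B-like cells lay mostly in cluster 3 in the control (74.6%) and PBS week 2 (69.0%), in cluster 0 in PBS week 4 (69.9%), and in cluster 1 in cGAMP week 2 (40.7%, with 31.8% in cluster 7 and 21.6% in cluster 8) and cGAMP week 4 (57.8%). Most CD4 T-like cells lay in cluster 4 with PBS and in cluster 10 with cGAMP, CD8 T-like cells in clusters 5 and 9, and macrophage- or monocyte-like cells in clusters 23 and 14.

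**Figure D3:**
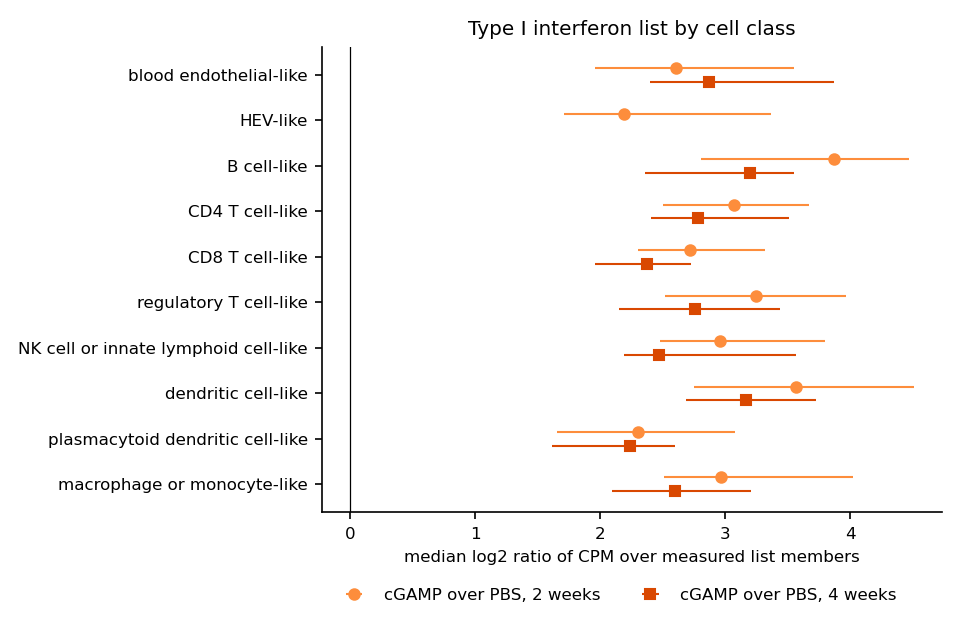
Median log2 ratio of the type I interferon list by cell class for cGAMP over PBS (circles week 2, squares week 4), with bars for the 95% interval of the median over list members. The cGAMP medians lie between 2.24 and 3.87 in the immune classes and at 2.61 and 2.87 in blood endothelial-like cells.

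Macrophage- or monocyte-like cells were 1.02% (0.809 to 1.27) of immune cells in the control, 0.759% (0.641 to 0.893) in PBS week 2, 7.19% (6.78 to 7.62) in cGAMP week 2, 1.17% (1.08 to 1.26) in PBS week 4 and 3.81% (3.58 to 4.06) in cGAMP week 4. The ratio of shares with cGAMP over PBS was 9.47 (7.95 to 11.4) at week 2 and 3.27 (2.95 to 3.63) at week 4, after the same MACS enrichment and mixing. With the mitochondrial limit at 10% it was 6.62 (5.50 to 8.03) and 1.82 (1.64 to 2.03). B-like cells were 29.0%, 50.1%, 48.8%, 65.0% and 64.7% of immune cells, and dendritic-like cells 3.11%, 1.46%, 1.16%, 1.14% and 1.07%. In macrophage- or monocyte-like cells the MHC class II medians with cGAMP were -1.86 and -1.26, with Cd74 3.56-fold (3.45 to 3.67) and 2.4-fold (2.34 to 2.45) lower and H2-Aa 5.05-fold (4.83 to 5.28) and 4.03-fold (3.89 to 4.17) lower. Their proliferation medians were -2.69 and -1.79, and Stmn1 was 11.8-fold lower (9.08 to 15.4) at week 2. The makeup of the class differed, since cluster 14 held 89.0% and 85.7% of its cells with cGAMP at weeks 2 and 4. With PBS that cluster held 2.78% and 4.94%, so these medians compare largely different kinds of cells. All genes of this class had medians of -0.70 and -0.52, and with TMM factors, which bring these to 0.10 and 0.03, the class II medians were -1.05 and -0.71 and the proliferation medians -1.89 and -1.24. Cytotoxic effectors had medians of 1.32 and 1.5 in CD8 T-like cells and 1.13 and 1.41 in NK-like cells, all at percentile 100. Gzmb in NK-like cells stood at 13939 against 552 CPM at week 2 and 11826 against 540 CPM at week 4. In CD8 T-like cells Gzmb stood at 376 against 10.4 CPM at week 4, 36.1-fold higher (29.1 to 45.4), while Klrd1 was 1.79-fold (1.67 to 1.93) and 2.08-fold (1.96 to 2.20) lower at weeks 2 and 4.

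For PBS week 4 over week 2 the T cell exhaustion list had medians of 0.97 in CD4 T-like, 0.64 in CD8 T-like and 0.84 in regulatory T-like cells, each at percentile 100, and 0.94 in B-like cells. Nr4a3, a gene induced by antigen receptor signals, was 6.47-fold higher (5.48 to 7.67) in CD4 T-like, 4.70-fold (4.02 to 5.51) in CD8 T-like and 6.67-fold (5.55 to 8.08) in B-like cells. Ctla4 was 2.34-fold higher (2.16 to 2.54) in regulatory T-like cells. Median UMIs per cell were 1450 and 1708 in CD4 and CD8 T-like cells of PBS week 4, against 2400 and 2921 in PBS week 2. Whether a difference between the libraries as a whole lies behind these values was not tested. Melanoma-like cells were read in PBS week 4 alone, where there were 770, or 1.46% (1.36 to 1.56) of kept cells. The other libraries held 0, with upper interval bounds of 0.0467%, 0.0193%, 0.0247% and 0.0149% in the control, PBS week 2, cGAMP week 2 and cGAMP week 4. Of these, 636 cells of cluster 24 had a median of 34066 UMIs, and 134 of cluster 34 a median of 914. Together they held 7632 CPM of Dct and 3523 CPM of Pmel, both genes of pigment synthesis, against 44.8 and 17.2 CPM in B-like cells of that library. The melanoma list was correspondingly higher in B-like cells of PBS week 4 than of PBS week 2 (7.15, or 5.29 with the 7 members at 0 at their bound) and the control (5.56, or 3.71).

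**Figure D4:**
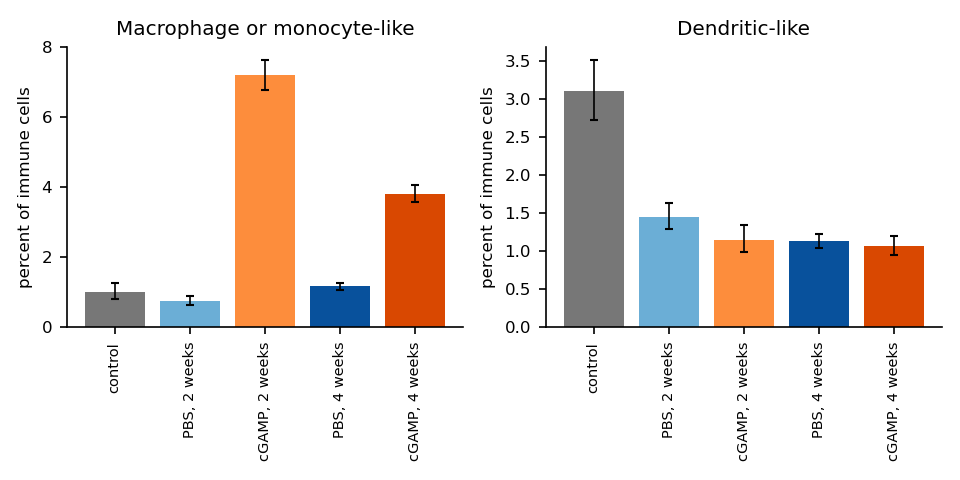
Shares of macrophage- or monocyte-like and dendritic-like cells among immune cells in the 5 libraries, in percent, with bars for 95% Clopper-Pearson intervals. Macrophage- or monocyte-like cells make up 7.19% in cGAMP week 2 and 3.81% in cGAMP week 4.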

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

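The tests in this part were chosen after the results were seen. A technical account of each pattern is set beside the treatment. Each group had 1 library, so only differences between cGAMP and PBS have a second pair, at the other week.

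Vessels of cGAMP libraries carried far more interferon-induced RNA than those of PBS libraries, with type I interferon medians of 2.61 and 2.87. Free RNA from immune cells could account for a median of 3.15% (2.80 to 4.12) of the CPM of the members at week 2 and 2.28% (2.11 to 2.84) at week 4, using the larger of the free RNA estimates. The difference held within HEV-like cells at week 2 with a median of 2.19 (1.71 to 3.37). Without HEV-like cells at week 4 it was 3.31 (2.47 to 4.06). These values argue against a changed mix of HEV-like and other cells alone. They cannot address a mix within each, as sub-cluster 2 held 39 HEV-like cells of cGAMP week 2 and 0 of PBS week 2. Likewise, sub-cluster 4 held 13 other cells of cGAMP week 4 and 0 of PBS week 4. With both clusterings made without the listed interferon genes it was 2.60 (1.96 to 3.55) and 2.93 (2.4 to 3.87), so the pattern did not need the listed genes to choose the cells. The endothelial cluster held 397 cells with and without them, with equal numbers per library, so only the sub-clustering could change the class. Other interferon-induced genes were not left out, so a part for them stays open. The difference recurred in both pairs of libraries, and a fit with week as a block called all 34 members higher. Whether endothelial cells responded to interferon made elsewhere or to cGAMP directly stays open.

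Macrophage- or monocyte-like cells were a larger share of immune cells with cGAMP, 9.47 times (7.95 to 11.4) that with PBS at week 2 and 3.27 times (2.95 to 3.63) at week 4. A lower share of lymphocytes in the loaded mix would raise dendritic-like cells alike, but their ratios were 0.794 (0.652 to 0.964) and 0.943 (0.813 to 1.09). The size depends on the mitochondrial limit, as at 10% the ratios were 6.62 (5.50 to 8.03) and 1.82 (1.64 to 2.03), with 0.554 (0.452 to 0.678) and 0.493 (0.422 to 0.573) for dendritic-like cells. The listed interferon genes did not decide the class, since the ratios were 9.47 (7.95 to 11.3) and 3.25 (2.93 to 3.60) with clusterings made without them. Other interferon-induced genes were not left out, so a part for them stays open. A better yield of the whole class would raise each of its clusters if cells kept their kind. With those clusterings cluster 18 was lower with cGAMP, at 0.7148 (0.517 to 0.981) and 0.391 (0.310 to 0.489) times its share with PBS. Cluster 30 was higher, at 4.635 (2.98 to 7.46) and 2.043 (1.51 to 2.77) times, and cluster 14 held 907 cells against 5 and 758 against 17. Cells that changed from the cluster 18 kind to the cluster 14 kind would also lower cluster 18, so this test cannot decide on yield. Such a change alone would leave the share of the class as it was. More cells of the class in the node, or a better yield of all or some of its kinds, may lie behind the difference.

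Melanoma-like cells, a signal outside the planned comparisons, numbered 770 in PBS week 4, or 1.46% of its kept cells, against 0 in the other libraries. Free RNA in poor barcodes is argued against for the 636 cells of cluster 24, of which 100% (99.4 to 100) held more UMIs than the median kept cell of the library, 1244. For the 134 cells of cluster 34 this share was 33.58% (25.7 to 42.3), so that account stays open for them. Whether these cells grew in the node or came from tumour tissue taken along at dissection cannot be told apart at 1.46% (1.36 to 1.56), as no label decides it. Nor can it be told whether blood endothelial-like cells of this library came with such tissue.

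Several lists differed in direction between the weeks, and these differences were not tested. MHC class II in blood endothelial-like cells was 1.09 for cGAMP over PBS at week 2 (percentile 99.92 among random lists) and -0.84 at week 4 (percentile 0.62). In regulatory T-like cells the same list was 0.92 (99.99) and -1.20 (0.00), and hypoxia and glycolysis was 0.19 (98.44) and -0.21 (1.44). In dendritic-like cells proliferation was -0.40 (1.33) and 0.12 (98.54) for cGAMP over PBS, and angiogenesis was 0.36 (99.51) and -0.51 (0.82) for PBS over control. MHC class II RNA is abundant in B-like cells. Free RNA may enter the class II values of blood endothelial-like and of regulatory T-like cells, which went the same way at each week. With free RNA subtracted as planned those of blood endothelial-like cells were 2.02 and -1.64. At the immunoglobulin estimates they were 2.02 and -0.57, so the week 4 value depends on the estimate. The B cell transcript Igkc stood at 97.9 against 122 CPM in blood endothelial-like cells at week 2 and 313 against 580 CPM at week 4. It thus went the same way as class II at week 4 alone. Igkc cannot show class II RNA from macrophage- or dendritic-like cells, so a part for these stays open at both weeks.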

How the results depend on the processing

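Of the alternatives in this part, those with clusterings made without the interferon lists, doublets called by scrublet's own threshold, sub-cluster 7 left out, 1 control cell added, free RNA subtracted at the immunoglobulin estimate, and the minimum of 20 cells were chosen after the data were seen. A value counted as moved when it left the 95% interval of the main value. For list medians this interval describes the spread over members and is wide for short lists, so staying within it is a weak criterion. Where it spans 0, a change of sign within it counted as the same. No paired analysis was possible because the groups share only 1 replicate number. With week as the block in place of a replicate, an edgeR quasi-likelihood fit of cGAMP against PBS on the 4 tumour libraries, chosen after the data were seen, called 357 genes higher and 132 lower of 8348 in blood endothelial-like cells at a Benjamini-Hochberg adjusted p under 0.05. All 34 type I interferon members were called higher there, with a median log2 ratio of 2.80. In the 8 immune classes every member tested was called higher except 1 of 32 in plasmacytoid dendritic-like cells, with medians of 2.37 to 3.72. The crossed split of the libraries set cGAMP week 2 and PBS week 4 against the others. It called 0 genes in each of these classes, and its interferon medians lay between -0.12 and 0.32. In this split the difference between cGAMP and PBS falls into the residual. Few calls were therefore likely in advance, and the split does not measure false calls of the treatment fit.

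For the type I interferon, proliferation and HEV programme lists, 37 medians gave 448 values under the alternatives, of which 434 stayed within the interval, 11 moved and 3 reversed. For the other lists 933 of 963 values stayed, 30 moved and 0 reversed. Among 90 values of shares 80 stayed and 10 moved. Single genes stayed in 1239 of 1332 values, moved in 90 and reversed in 3. No type I interferon median for cGAMP over PBS moved under any alternative run, in blood endothelial-like or immune classes. A stricter limit on mitochondrial UMIs, members of at least 100 UMIs and the class without HEV-like cells left too few cells or members for some medians, which then have no value.

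With CPM averaged over cells, the type I interferon median in blood endothelial-like cells was 0.44 for PBS week 2 over control and -0.24 for PBS week 4 over PBS week 2, and the proliferation median for PBS week 2 over control was 3.35. With scrublet's own threshold, proliferation was 3.38 for PBS week 2 over control, -2.61 for cGAMP over PBS at week 2 and 1.07 for PBS week 4 over PBS week 2, and the lymphatic-like share of PBS week 2 was 0%. Without sub-cluster 7, proliferation was 1.85 for PBS week 2 over control and -1.11 for cGAMP at week 2, as this alternative leaves out the sub-cluster with the most proliferation RNA. The clusterings without the interferon lists gave 0.37 for PBS week 2 over control, and the addition of the 1 control cell that joins there gave 0.41 alone, so this cell is the cause.

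With HEV-like cells left out, proliferation for cGAMP at week 2 was -5.07, proliferation for PBS week 4 over PBS week 2 reversed to -0.42, and the HEV programme of that pair reversed to 0.25, since the class then lacks the cells that carry it. Of the single genes, Rgs5 for cGAMP at week 4 reversed to 2.64, and Serpina3n and Mustn1 for PBS week 4 over PBS week 2 reversed to 0.44 and 1.66. With members of at least 100 UMIs, proliferation of that last pair reversed to -0.17. The cause was not tested for these genes, for the averaged CPM, for scrublet's threshold or for the member minimum.

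A mitochondrial limit of 10% gave macrophage- or monocyte-like shares of 1.58%, 1.38%, 9.15%, 3.08% and 5.61% in control, PBS week 2, cGAMP week 2, PBS week 4 and cGAMP week 4, and a melanoma-like share of 3.17%. In PBS week 4 this limit left 27.4% of B-like, 94.1% of macrophage- or monocyte-like and 79.0% of melanoma-like cells, so the loss of B-like cells raises these shares there. With at least 500 genes and 1000 UMIs per cell these shares were 1.49% and 1.74% in PBS week 4, and with doublets kept the macrophage- or monocyte-like share of cGAMP week 2 was 7.66%. The shift of all genes for cGAMP over PBS at week 2 was -0.16, or 0.05 with TMM factors. Depth limits the endothelial results, as 30 or 31 cells stand behind the control and both week 4 libraries.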

Other observations

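In blood endothelial-like cells Ackr1 stood at 834, 463, 1149, 221 and 673 CPM in control, PBS week 2, cGAMP week 2, PBS week 4 and cGAMP week 4. Ifng in CD8 T-like cells stood at 1.57, 4.51, 11.4, 1.49 and 15.7 CPM in the same order. Exhaustion genes in CD8 T-like cells had medians of 0.70 and 0.28 for cGAMP over PBS at weeks 2 and 4. In B-like cells MHC class II stood at -0.26 and -0.16 with cGAMP, and in dendritic-like cells at -0.82 and -0.57.

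Neutrophil-like cells made up 0.357%, 0.221%, 0.432%, 0.593% and 0.0812% of immune cells, and plasma-like cells 0.127%, 0.111%, 0.108%, 0.436% and 0.337%. Plasmacytoid dendritic-like cells made up 1.43%, 0.480%, 0.263%, 0.555% and 0.231%. Regulatory T-like cells made up 1.85%, 2.06%, 1.47%, 2.20% and 2.22%, and NK-like cells 1.20%, 0.991%, 1.59%, 0.969% and 0.994%. T-like cells of no clear subset made up 47.0%, 18.9%, 10.9%, 5.94% and 1.99% and were not compared. Clusters without a name held 25, 10, 0, 1943 and 2 cells, and proliferating clusters without a name held 221, 398, 211, 678 and 471. Of Ifnb1, 2 UMIs were read in macrophage- or monocyte-like cells of cGAMP week 4 and 1 in CD8 T-like cells of PBS week 4.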
